A study of Mus musculus with 16 samples.

How the data were processed

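RNA was sequenced from the proximal jejunum of male CBA/J mice in 16 libraries, which form 4 groups of 4 by diet and radiation dose. Per the labels' protocols, ribosomal RNA was removed with a kit, the remaining RNA was fragmented, and libraries were built with a small RNA library protocol, which ligates adapters to RNA directly. Per the submitters' processing notes, reads were aligned with Bowtie2 2.2.9 and counted with RSEM 1.3.0 on genome build NCBIM37, and edgeR 3.2.4 is named as well. The deposited values used here are RSEM expected counts, that is, estimated counts per gene, with 1 file per library and the unit named per the file headers. RSEM shares reads that fit several genes among them, so values are not all whole numbers, and they were rounded to whole numbers before testing. The authors' own test results were not among the files.

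Each file lists 37620 Ensembl gene IDs. Symbols and gene types came from the GENCODE M21 annotation, which gave a symbol for 32897 IDs and none for 4723. That annotation belongs to a later genome build than the one the submitters name, so it served for names, types and lengths alone and no chromosome position is given. The IDs without a symbol stayed in the tests, and they held between 4.4 and 8.41% of a library's counts. A group of 125 tested genes had counts identical to another gene in all 16 libraries, as happens for copies that share their reads, and this is stated where such a gene is named. The mean length per gene is the one the files give.

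Groups were taken from the labels. Replicate numbers follow the order of the deposited samples and pair no libraries. The labels name neither a batch nor a date, and they give no identifier of the animal behind a library. All p-values therefore measure the spread between libraries, which the design text lets be read as spread between mice. Within groups, the correlation of log2 CPM between libraries lay between 0.922 and 0.983 with a median of 0.966. The difference in counts between any pair of libraries of a group was at least 9.48 times what counting error gives (chi-square per degree of freedom), so within groups no library was a copy of another. Pairs across groups were not compared in this way.

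Genes were kept by filterByExpr of edgeR 4.0.16 with the 4 groups, which left 16558 genes. Libraries were scaled by TMM factors. A negative binomial model with a mean per group over the 16 libraries was fitted with robust dispersions, and comparisons were tested with edgeR's quasi-likelihood F test in R 4.3.3, two-sided. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.219. Fold changes are log2 with their standard error (SE), and CPM values rest on TMM-scaled totals, given as mean ± SD of 4 libraries. The comparisons were radiation on each diet, diet at each dose, and the diet by radiation interaction, which is the response to radiation on the supplemented diet minus that on the adequate diet. Genes called on both diets in the same direction were counted beside the number that independent lists of those sizes would share.

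The analysis rested on 38 gene lists of cell types, pathways and RNA classes, fixed with their members before the data were examined. Each list was tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the 38 lists of a comparison. Camera asks whether a list moved relative to the other genes. The same test with a correlation estimated from these libraries was run as an alternative, and fry, which asks whether the members moved on balance in a direction without comparing them with other genes, was run beside it. Where the text says that a member count is adjusted over the list alone, Benjamini-Hochberg was applied to the members of that list.

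The genes named in the text follow a rule fixed before the data were examined. They are, first, the 8 called genes with the largest rise and the 8 with the largest fall in each comparison that had a mean log2 CPM of at least 1 and no overlap between the 4 libraries of each group, without unnamed genes, predicted genes, receptor segments, small RNAs and pseudogenes. They are, second, the 2 members with the smallest p of each list that passed camera or had at least 3 called members. They also are Cdkn1a, Mdm2, Mki67, Lgr5, Olfm4, Lyz1, Alpi, Bhmt, Mat2a and Dnmt1 in every comparison. A gene could be left out where another comparison names it. Bhmt did not pass the filter on low counts and has no value. Some genes that this rule names, or that belong to a small count, are not reported. Genes named only to identify a small count, and Cela2a as the gene called in opposite directions, were chosen after their values were seen.

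Depth was between 2.57 and 15.51 M counts per library. For a gene at 0 in all 4 libraries of a group, the limit is 3 counts over the pooled libraries of the group, and bounds on fold changes use that limit. Intervals for pooled low counts are exact Poisson intervals at 95% confidence. Limits and intervals cover counting error alone. Shares of RNA types and list means were compared between groups with exact two-sided permutation tests of the difference in means, whose smallest possible p with 4 libraries per group is 0.0286.

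The alternatives were RLE or upper-quartile factors in place of TMM, no filter beyond 1 count, a filter of 1 CPM in 8 libraries, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, a fit with the compared groups alone, removal of the 20 genes of highest count, protein-coding genes alone, an adjusted p under 0.01, camera with an estimated correlation, and leaving out each library in turn. Leaving out the 3 libraries under 4 M counts together was added after seeing the data. The fit of compared groups alone does not apply to the interaction, which needs all 4 groups. Every comparison was also repeated with the libraries regrouped, over all 35 splits of 8 libraries or 100 drawn splits where the design has more.

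The tests were run on simulated counts with the levels, dispersions and library sizes of these data and known changes. For radiation on the adequate diet, edgeR found 51% of 2-fold and 92% of 4-fold changes, and 4.6% of its calls were false. For diet at 0 Gy it found 54 and 88% with 7.7% false, for diet at 8.5 Gy 55.6 and 89% with 4.5% false, and for the interaction 28 and 72.7% with 8.3% false. The false share of DESeq2 in those simulations was 12.6, 18.7, 10.2 and 18.9%. Camera called a simulated 1.5-fold rise of 1 list in all 4 simulated comparisons and called 0 other lists. Genes were simulated independently of each other, without the correlation that real genes have. The simulation therefore cannot tell how often camera calls a list by chance in these libraries. Radiation on the supplemented diet was not simulated.

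No ready-made gene set collection was used, isoform values were not analysed, and no library was left out of the reported values.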

Results

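Gene expression was measured by RNA sequencing in the proximal jejunum, the upper middle part of the small intestine, of male mice of the inbred strain CBA/J at 8 weeks of age. The 16 libraries formed 4 groups of 4 that crossed a methionine-adequate or methionine-supplemented diet with exposure to gamma rays, at a dose of 0 or 8.5 Gy. The design text gives the supplementation as 300% and a period of 6 days, without saying whether that period is the time on the diet or the time after irradiation. In the unirradiated adequate group, replicates 1 to 4 had 2.57, 10.68, 9.52 and 9.61 M (mega) counts, and in the irradiated adequate group 10.21, 2.85, 10.91 and 11.44 M. The supplemented groups had 8.77, 8.77, 9.67 and 9.24 M counts without irradiation and 3.43, 15.51, 15.27 and 11.78 M with it. Of 37620 genes in the files, 16558 were tested. The first principal component held 30.8% of the variance, and its scores lay between -53.7 and -16.5 in the 8 unirradiated libraries and between 16.7 and 63.7 in the 8 irradiated ones.

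The make-up of the libraries differed between the groups. Small nucleolar RNAs, which guide the modification of ribosomal RNA, took 3.58 ± 0.478% of counts without and 8.57 ± 1.51% with irradiation on the adequate diet (mean ± SD, n = 4 per group), and 4.04 ± 0.986% and 11.3 ± 2.70% on the supplemented diet. Protein-coding genes took 76.9 ± 1.20% and 69.4 ± 0.990% on the adequate diet and 80.0 ± 2.05% and 70.7 ± 4.67% on the supplemented diet. Mitochondrial ribosomal RNAs took 4.68 ± 0.832% and 5.46 ± 1.26% on the adequate diet, against 2.17 ± 0.395% and 2.19 ± 0.703% on the supplemented diet. The exact two-sided permutation p was 0.0286 for small nucleolar RNAs and protein-coding genes between doses on each diet, and for mitochondrial ribosomal RNAs between diets at each dose, which is the smallest p that 4 against 4 libraries allow. With Benjamini-Hochberg adjustment over the 28 such tests these p-values became 0.0801.

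**Figure D1:**
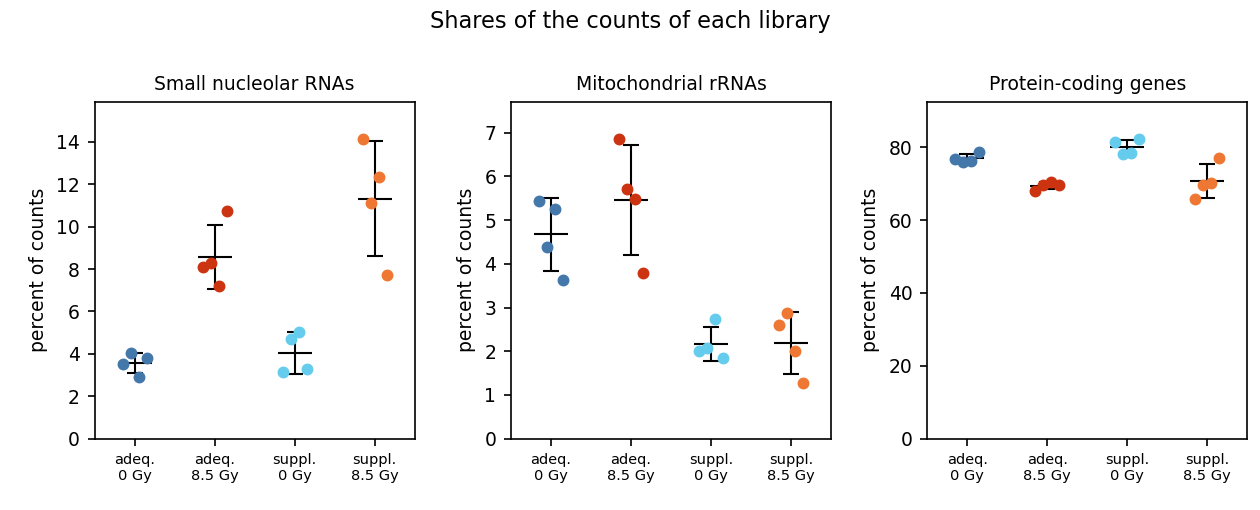
Shares of each library's counts (percent) taken by small nucleolar RNAs, mitochondrial ribosomal RNAs and protein-coding genes in the 4 groups. Points are libraries and bars show mean ± SD (n = 4). The irradiated libraries of the adequate diet held 7.18 to 10.7% small nucleolar RNA against 2.93 to 4.03% in the unirradiated ones.

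Radiation on the adequate diet was the first comparison, which asks what 8.5 Gy changed when methionine intake was adequate. Lists of antimicrobial genes, of Paneth cells, the defence cells at the crypt base, and of goblet cells, which make mucus, rose, with 9 of 15, 13 of 14 and 10 of 19 genes called. Reg3b, an antimicrobial lectin of the epithelium, went from 23.2 ± 5.06 to 4196 ± 1822 CPM (log2 fold change 7.49 ± 0.51, adjusted p = 2.63e-07, n = 4 per group). Hba-a1, an alpha globin of red blood cells, went from 65.6 ± 16.2 to 1.77 ± 0.530 CPM (-5.35 ± 0.40, adjusted p = 1.48e-06). Lower calls took in 9 of 10 B cell, 7 of 20 cholesterol synthesis and 8 of 27 interferon-stimulated genes, of which Cxcl9 was higher, and these lists had an adjusted p = 0.159, 0.155 and 0.355 with an estimated correlation. The lists of the S phase and of the G2 and M phases had 0 called members among 26 tested each.

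In this comparison, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1180 genes higher and 1090 lower of 16558, and 820 of the 2270 changed more than 2-fold. The 8 named genes with the largest rise were Reg3b, Defa3, Mptx2 (log2 6.64 ± 0.48), Reg3g (5.73 ± 0.36, from 37.1 ± 7.01 to 1963 ± 690 CPM), Defa37 (5.14 ± 0.54), Defa5 (4.87 ± 0.48), Bcl2l15 (4.47 ± 0.65) and Defa35 (4.37 ± 0.23, adjusted p = 1.53e-08). The Defa genes encode alpha-defensins, antimicrobial peptides of Paneth cells, Mptx2 is a mucosal pentraxin, Reg3g is a lectin like Reg3b, and Bcl2l15 belongs to the Bcl-2 family. Defa3 was at 0 in 3 of the 4 unirradiated libraries, with 1.27 CPM over the pooled group (95% interval 0.909 to 1.72) against 205 CPM in the irradiated group. Its fitted log2 fold change was 6.97 ± 1.58. Without unirradiated replicate 1, the library that held its counts, the bound was 2036-fold higher with irradiation, taking 3 counts over the group as the limit. That bound covers counting error alone and not the spread between libraries. Among unirradiated libraries of the supplemented diet, Defa3 was at 0 in replicate 2 and at 67.3 to 88.5 CPM in the others. The 8 with the largest fall were the globins Hbb-bt, Hba-a2 (-7.29 ± 1.06), Hbb-bs (-7.20 ± 0.81) and Hba-a1, then Apoa2 (-4.79 ± 0.56), Acta1 (-4.03 ± 1.15), Tkfc (-2.61 ± 0.61) and Fbp1 (-2.35 ± 0.62). Hbb-bt had 0 counts in all 4 irradiated libraries and was at least 267-fold lower, taking 3 counts over the group as the limit. Apoa2 is an apolipoprotein, Acta1 the actin of skeletal muscle, Tkfc a kinase of fructose breakdown and Fbp1 an enzyme of gluconeogenesis.

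Among the lists of epithelial cells on the adequate diet, 13 of 14 tested Paneth cell genes rose and 0 fell (median log2 fold change 1.80; 13 higher and 1 lower adjusted over the list alone), with Mmp7, the protease that activates defensins, at 2.25 ± 0.19 and Lyz1, the lysozyme of Paneth cells, at 1.52 ± 0.21 (1027 ± 199.8 to 2937 ± 361 CPM). In the list of antimicrobial and acute-phase genes of the epithelium, 9 of 15 rose and Reg3a fell (median 1.85; 10 higher and 2 lower adjusted over the list alone). Of 19 goblet cell genes, 10 rose and 0 fell (median 0.53; 11 higher adjusted over the list alone), among them Spink4 (1.64 ± 0.15, adjusted p = 3.86e-06) and Agr2, a protein folding factor of mucus cells (0.92 ± 0.16). Of 20 crypt base stem cell genes, 7 rose and 0 fell (median 0.48; 8 higher adjusted over the list alone), with the salt transporter Slc12a2 at 1.44 ± 0.22, Olfm4 at 1.32 ± 0.23 (191 ± 10.1 to 478 ± 208 CPM) and the stem cell receptor Lgr5 at 1.04 ± 0.24 (adjusted p = 0.00994). The stem cell list passed camera with an adjusted p of 0.000194, and it had an adjusted p = 0.524 with an estimated correlation. Of 18 enteroendocrine genes, 5 rose (median 0.60; 10 higher and 1 lower adjusted over the list alone), namely the granule protein Chgb (0.96 ± 0.18), the serotonin enzyme Tph1 (1.14 ± 0.22), Sct, Tac1 and Scg2. The enteroendocrine list had an adjusted p = 0.291 with an estimated correlation. In the list of regenerating, fetal-like epithelium, 5 of 16 rose (median 0.63; 8 adjusted over the list alone), among them S100a6 (1.51 ± 0.23), Anxa1, Ereg and Spp1, and the list had an adjusted p = 0.0781 with an estimated correlation. Of 27 absorptive enterocyte genes, the peptidase Enpep (1.40 ± 0.38), the amino acid transporter Slc6a19 (1.71 ± 0.48) and Slc15a1 rose and Slc2a5 fell, and the list did not pass (median 0.09, adjusted p = 0.847). Irradiated replicate 4 went the other way, with Enpep at 246 CPM (323 to 556 in the unirradiated libraries) and Slc6a19 at 143 CPM (225 to 324). Tuft cell genes had Alox5 and Il17rb lower of 11, and ileal enterocyte genes Clec2h higher and Nr0b2 lower of 5, with neither list past camera. The mean level of the absorptive list spread more among the irradiated libraries (9.98 ± 0.637) than among the unirradiated ones (10 ± 0.086 log2 CPM).

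**Figure D2:**
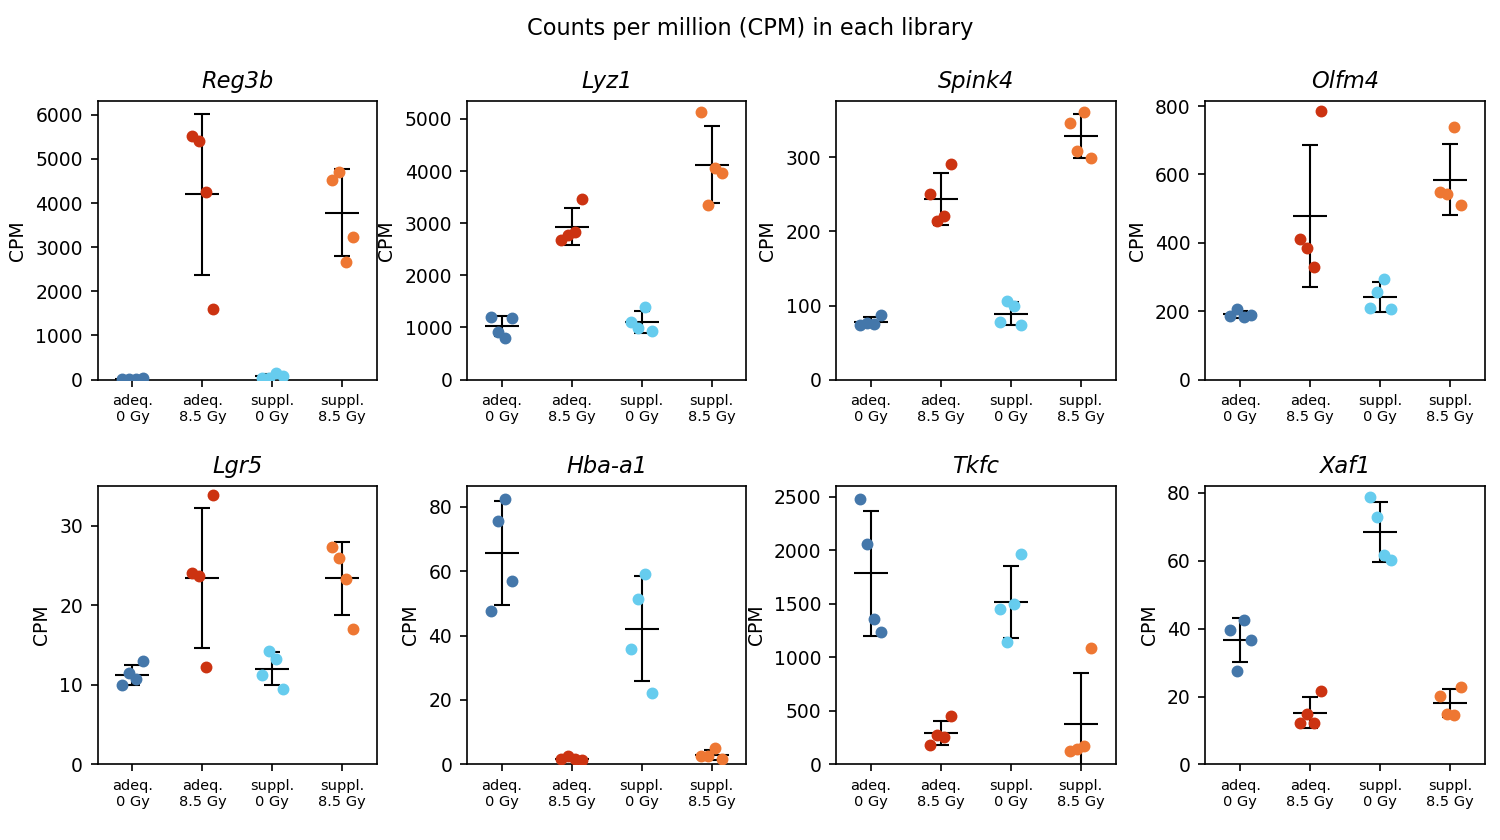
CPM of 8 genes in each library of the 4 groups, on linear axes that start at 0. Points are libraries and bars show mean ± SD (n = 4). For Lyz1 the irradiated libraries lay above the unirradiated ones on both diets, with group means of 2937 against 1027 CPM on the adequate and 4125 against 1109 CPM on the supplemented diet.

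Among the lists of damage and metabolism on the adequate diet, 5 of 28 p53 target genes rose and 0 fell (median 0.24; 6 higher adjusted over the list alone), namely the signalling inhibitor Phlda3 (1.69 ± 0.26), the receptor Eda2r (2.84 ± 0.47), Pmaip1, Zmat3 and Plk3. Cdkn1a, the cell cycle inhibitor induced by p53, had a log2 fold change of 0.17 ± 0.31 (adjusted p = 0.766), and Mdm2, the ligase that degrades p53, one of 0.26 ± 0.18 (0.357). Mki67, a marker of cycling cells, had 0.43 ± 0.26 (0.289). All 20 cholesterol synthesis genes had negative fold changes and 7 passed (median -0.43; 10 lower adjusted over the list alone), with the sterol sensor partner Insig1 at -2.20 ± 0.33 and the isoprenoid enzyme Fdps at -1.02 ± 0.16. The cholesterol list had an adjusted p = 0.155 with an estimated correlation. Among NRF2 and glutathione genes 6 of 24 rose, with the peroxidase Gpx2 at 1.56 ± 0.24, and the transferases Gstp1 (-0.88 ± 0.15) and Gsta4 fell (median -0.07, mean 0.10). Of 23 genes of the ATF4 and endoplasmic reticulum stress list, Asns, Nupr1, Vldlr and Slc7a5 rose, and the proline synthesis enzyme Aldh18a1 (-1.53 ± 0.23) and Ddit3, a stress transcription factor (-0.94 ± 0.18), fell. Of 18 circadian clock genes Per1 (1.27 ± 0.28) and Tef rose, and Hlf (-1.21 ± 0.26), Arntl and Bhlhe40 fell (median 0.01, mean -0.01), and Per1 was not called without the 3 libraries under 4 M counts (1.19). Of 25 genes of the methionine cycle and transsulfuration, Srm, which makes spermidine, rose (0.80 ± 0.22), and Cth, which makes cysteine (-0.65 ± 0.12), and Ahcyl1 fell. Mat2a, which makes S-adenosylmethionine, had 0.29 ± 0.14 (adjusted p = 0.181). Of 18 DNA methylation genes Zbtb33 (0.67 ± 0.13) and Mbd2 rose and the methyltransferase Dnmt3a (-0.62 ± 0.12) and Mbd3 fell, while Dnmt1 had -0.01 ± 0.18 (0.976). Of 19 folate genes 3 rose, among them Fpgs (0.86 ± 0.18) and Atic (0.58 ± 0.17). Pdk4 rose among 20 lipid oxidation genes and Xrcc5 and Brip1 among 26 DNA break repair genes, Cyp4f14 and Ces2e fell among 20 xenobiotic genes. None of these lists, nor the 6 lists before them from NRF2 on, passed camera. Alpi, an alkaline phosphatase of enterocytes, had 0.55 ± 0.36 (0.335).

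Markers of other cell types also moved on the adequate diet. All 5 tested red blood cell genes fell (median -7.20, and -7.20 with Hbb-bt at its bound). The red blood cell list had an adjusted p = 0.0781 with an estimated correlation. Of 10 B cell and plasma cell genes 9 fell (median -1.51; 10 adjusted over the list alone), with Jchain at -1.5 ± 0.26 and Mzb1 at -1.81 ± 0.33, both of antibody-secreting cells. The B cell list had an adjusted p = 0.159 with an estimated correlation. Of 27 interferon-stimulated genes 8 fell and Cxcl9 rose (median -0.73; 15 lower and 2 higher adjusted over the list alone), with Xaf1 at -1.25 ± 0.20 and the antiviral Mx2 at -1.40 ± 0.23. The interferon list had an adjusted p = 0.355 with an estimated correlation. In the list of macrophages, dendritic cells and neutrophils Itgam, Lyz2, Cd14, Mrc1 and Fcgr3 rose of 24 and the dendritic cell genes Clec9a (-1.5 ± 0.26) and Flt3 (-1.62 ± 0.35) fell, and the list had an adjusted p = 0.818 with an estimated correlation. Of 20 fibroblast and matrix genes the proteoglycan Dcn (1.20 ± 0.20), Col6a1, Mmp2 and Timp1 rose and 0 fell (median 0.47; 5 adjusted over the list alone). The fibroblast list had an adjusted p = 0.525 with an estimated correlation. In the inflammatory list Icam1 (0.95 ± 0.22), the chemokine Ccl2 (2.58 ± 0.66) and Selp rose of 14 (median 0.67; 6 adjusted over the list alone). The inflammatory list had an adjusted p = 0.287 with an estimated correlation. Of 19 T cell and intraepithelial lymphocyte genes Gzma and Gzmb rose and Cd8b1 (-2.91 ± 0.63) and the integrin Itgae (-0.79 ± 0.20) fell. Of 5 mast cell genes Mcpt1 and Mcpt2 fell. Of 13 exocrine pancreas genes Rnase1 (1.99 ± 0.28) and Clps (0.55 ± 0.17) rose and Cela2a fell (median -0.46, test upwards at an adjusted p of 0.948). Mmrn1 rose among 18 endothelial genes, Mylk fell among 18 smooth muscle genes, and 0 of 12 enteric neuron and glia genes were called, with none of these 6 lists past camera.

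Non-coding and mitochondrial RNA moved as well on the adequate diet. Of 108 small nucleolar RNAs 60 rose and Snora23, Snord73a and Snora5c fell (median 0.92; 76 higher and 5 lower adjusted over the list alone), with Snord87 at 2.59 ± 0.31 and Snord1b at 2.07 ± 0.21. The small nucleolar RNA list had an adjusted p = 0.0846 with an estimated correlation. Of 9 RNAs listed as small nuclear or 7SK, Rnu73b (1.98 ± 0.19), Rnu1b6, equal in counts to a copy (2.55 ± 0.29), Rnu11 and Rnu12 rose and 0 fell (median 0.97; 5 higher and 1 lower adjusted over the list alone). Of 13 mitochondrially encoded messenger RNAs 12 rose (median 1.23; 12 adjusted over the list alone), with mt-Nd6 at 1.67 ± 0.16 and mt-Nd2 at 1.5 ± 0.20. The mitochondrial list had an adjusted p = 0.0563 with an estimated correlation. Of 52 replication-dependent histone genes 6 rose (median 0.34; 6 adjusted over the list alone), with Hist2h2ac at 1.28 ± 0.20 and Hist1h2ad at 1.51 ± 0.28. The histone list had an adjusted p = 0.881 with an estimated correlation. Of the 18 lists that passed camera in this comparison, the antimicrobial (0.00434), goblet cell (0.031), small nuclear RNA (0.031), Paneth cell (0.0462) and p53 target (0.0462) lists also passed with an estimated correlation.

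Limma voom called 1813 genes higher and 1770 lower in the comparison of doses on the adequate diet, an adjusted p under 0.01 left 485 and 386. Leaving out the 3 libraries under 4 M counts, chosen after seeing the data, left 814 and 624. Without irradiated replicate 1 the counts were 690 and 541, without unirradiated replicate 2 they were 795 and 697. Without irradiated replicate 4 the median was 0.22 for stem cell genes, 0.22 for fibroblast genes, -2.29 for B cell genes and -0.003 for histone genes, whose list did not pass then or without unirradiated replicate 1 (0.24). The macrophage list did not pass without unirradiated replicates 1 (0.24), 2 (0.23) or 3 (0.23) or irradiated replicate 4 (0.06). Single libraries also ended gene calls: unirradiated replicates 1 or 2 or any irradiated library for Acta1 (log2 -4.46 to -3.42 over the alternatives), irradiated replicates 1, 2 or 3 for Fbp1 (-2.77 to -2.20), and unirradiated replicate 2 for Ccl2 (2.04 to 2.99). The call of Srm ended without unirradiated replicates 3 or 4 or irradiated replicate 1 (0.70 to 0.93), that of Atic without any unirradiated library or irradiated replicates 1 or 4 (0.46 to 0.66), and that of Clps without unirradiated replicates 2 or 3 or irradiated replicates 1, 2 or 4 (0.38 to 0.63). Enpep lost its call without unirradiated replicates 2, 3 or 4 or irradiated replicates 1, 2 or 3 (1.12 to 1.73), and Slc6a19 without unirradiated replicates 1, 2 or 4 or irradiated replicates 1, 2 or 3 (1.44 to 2.07).

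Radiation on the supplemented diet was the second comparison, which asks the same question when methionine was supplemented. Lists of Paneth cell, goblet cell and antimicrobial genes again rose, with 12 of 14, 12 of 19 and 9 of 15 called. Lower calls took in 23 of 27 interferon-stimulated and all 5 red blood cell genes, and these lists had an adjusted p = 0.0867 and 0.119 with an estimated correlation. Mptx2 went from 2.14 ± 1.04 to 169 ± 38.7 CPM (log2 fold change 6.29 ± 0.44, adjusted p = 9.87e-07, n = 4 per group), and Reg3b from 78.5 ± 44.0 to 3784 ± 990 CPM (5.59 ± 0.47). The interferon-induced Ifit3 went from 342 ± 96.2 to 33.1 ± 12.3 CPM (-3.38 ± 0.40, adjusted p = 0.000121). Of 13 genes of the exocrine pancreas, a neighbouring organ, 9 were called higher (adjusted p = 0.139 with an estimated correlation for the list), at group means of the list of -0.13 ± 0.33 log2 CPM without and 1.21 ± 0.70 with irradiation.

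On the supplemented diet edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1329 genes higher and 1194 lower, and 896 of the 2523 changed more than 2-fold. The 8 named genes with the largest rise were Mptx2, Reg3b, Bcl2l15 (5.06 ± 0.64), Defa5 (4.48 ± 0.46), Reg3g (4.47 ± 0.34), the pentraxin Mptx1 (3.79 ± 0.41), the phospholipase Pla2g5 (3.54 ± 0.36) and Defa35 (3.30 ± 0.22, adjusted p = 2.52e-07). The 8 with the largest fall were Hbb-bt (-5.14 ± 0.91), Hba-a2 (-4.93 ± 0.88), Hbb-bs (-4.68 ± 0.69), Apoa2 (-3.75 ± 0.52), Ifi44 (-3.75 ± 0.84), Hba-a1 (-3.75 ± 0.35), Ifit3 and the RNA sensor Oas2 (-3.27 ± 0.44). Hbb-bt was at 0 in 3 of 4 irradiated libraries, and without irradiated replicate 3 it was at least 215-fold lower, taking 3 counts over the group as the limit. Hba-a2 had -7.61 without that library.

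Among epithelial lists on the supplemented diet, 12 of 14 Paneth cell genes rose (median 1.95; 12 higher and 1 lower adjusted over the list alone), with Mmp7 at 2.04 ± 0.19 and Lyz1 at 1.90 ± 0.21 (1109 ± 208 to 4125 ± 741 CPM). Of 15 antimicrobial genes 9 rose and 0 fell (median 1.59; 10 higher and 2 lower adjusted over the list alone), with the goblet cell protein Retnlb at 2.89 ± 0.21. Of 19 goblet cell genes 12 rose (median 0.65; 15 adjusted over the list alone), with Spink4 at 1.88 ± 0.15 and the secretory transcription factor Creb3l4 at 1.37 ± 0.21. Of 20 stem cell genes 8 rose (median 0.61; 9 adjusted over the list alone), with Prom1 at 1.22 ± 0.17, Olfm4 at 1.28 ± 0.23 and Lgr5 at 0.95 ± 0.24. The stem cell list had an adjusted p = 0.4 with an estimated correlation. Of 18 enteroendocrine genes 6 rose (median 0.54; 9 higher and 1 lower adjusted over the list alone), with Chga at 0.70 ± 0.15. The enteroendocrine list had an adjusted p = 0.4 with an estimated correlation. In the regenerating list 7 of 16 rose, with S100a6 at 1.54 ± 0.23, and Ly6a and the growth factor Areg (-2.08 ± 0.36) fell (median 0.47; 7 and 2 adjusted over the list alone). The regenerating list had an adjusted p = 0.186 with an estimated correlation. Of 27 absorptive enterocyte genes the fatty acid receptor Cd36 (1.60 ± 0.39) and Enpep rose and the fructose transporter Slc2a5 (-2.0 ± 0.57) and Slc2a2 fell, and the list did not pass (median 0.03, mean -0.03). Of 11 tuft cell genes 0 rose and 1 fell (median 0.00, mean -0.10), and Clec2h rose and Nr0b2 fell among 5 ileal enterocyte genes, with neither list past camera. Alpi had 0.22 ± 0.36 (adjusted p = 0.732), and the spread of the absorptive list again was larger with irradiation (9.83 ± 0.771 log2 CPM) than without (10 ± 0.153).

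Among the lists of damage and metabolism on the supplemented diet, 7 of 28 p53 targets rose (median 0.12; 8 higher and 1 lower adjusted over the list alone), with Eda2r at 2.86 ± 0.45 and Phlda3 at 1.5 ± 0.24. The p53 list had an adjusted p = 0.0867 with an estimated correlation. Cdkn1a had -0.29 ± 0.31 (adjusted p = 0.573), Mdm2 -0.11 ± 0.17 (0.731) and Mki67 0.23 ± 0.26 (0.6). The S phase list had Prim1 higher among 26, and the list of G2 and M phase genes had 0 called of 26. All 20 cholesterol genes had negative fold changes and 7 passed (median -0.38; 8 lower adjusted over the list alone), with Dhcr7 at -1.0 ± 0.18. The cholesterol list had an adjusted p = 0.186 with an estimated correlation. Of 24 NRF2 and glutathione genes Gpx2 (1.36 ± 0.24), Gstm1, Me1, Prdx1 and Gsr rose and Gsta4 and Gstp1 fell. Of 23 genes of the ATF4 list Vldlr (0.94 ± 0.15), the asparagine enzyme Asns (1.01 ± 0.18) and Nupr1 rose and Ddit3, Atf3 and Aldh18a1 fell. Of 20 lipid oxidation genes 2 rose, among them Cyp4a10, and the lipid droplet protein Plin2 fell (-1.12 ± 0.21). Of 20 xenobiotic genes Ugt1a1 (0.94 ± 0.25) and Cyp3a25 rose and Cyp4f14 (-1.47 ± 0.39) fell. Of 25 methionine cycle genes Cbs, which makes cystathionine, rose (2.07 ± 0.61), Cth and Odc1 fell, and Mat2a had 0.00 ± 0.14 (0.99). Of 19 folate genes 2 rose, among them Ggh (1.15 ± 0.19), and Aldh1l1 fell. Of 26 DNA break repair genes Xrcc5 (1.0 ± 0.18), Brip1 (0.42 ± 0.10) and Brca2 rose. Of 18 DNA methylation genes 2 rose, among them Mbd2 (median 0.02, mean -0.01), with Dnmt1 at 0.09 ± 0.18 (0.769), and of 18 circadian genes Cry2 rose and Hlf fell. None of these lists from NRF2 on passed camera.

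Other cell types and RNA classes on the supplemented diet included all 5 red blood cell genes, which fell (median -4.68). The red blood cell list had an adjusted p = 0.119 with an estimated correlation. The 23 lower interferon-stimulated genes had a list median of -1.64 (24 lower adjusted over the list alone), with Mx2 at -2.49 ± 0.23 and Xaf1 at -1.94 ± 0.20. The interferon list had an adjusted p = 0.0867 with an estimated correlation. Of 10 B cell genes Pou2af1 (-1.11 ± 0.33), Jchain, Cd79a and Derl3 fell (median -0.85; 6 adjusted over the list alone). The B cell list had an adjusted p = 0.4 with an estimated correlation. The 9 higher exocrine pancreas genes (list median 2.13; 10 adjusted over the list alone) included Rnase1 at 2.13 ± 0.27 and the lipase cofactor Clps at 0.90 ± 0.16, and the list had an adjusted p = 0.139 with an estimated correlation. Of 20 fibroblast genes 6 rose (median 0.40; 6 adjusted over the list alone), with Dcn at 1.53 ± 0.20 and the protease inhibitor Timp1 at 2.47 ± 0.44. The fibroblast list had an adjusted p = 0.47 with an estimated correlation. Among macrophage, dendritic cell and neutrophil genes 6 of 24 rose, with Lyz2 at 1.68 ± 0.27, and Flt3 (-1.96 ± 0.34) and Clec9a fell. Of 5 mast cell genes the proteases Mcpt1 (-3.14 ± 0.41), Mcpt2 (-2.85 ± 0.47) and Cpa3 fell and Kit rose. Cd8b1 and Itgae fell among 19 T cell genes, Mmrn1 and Lyve1 rose among 18 endothelial genes (median -0.10, mean 0.10), Nfkbia rose and Birc3 fell among 14 inflammatory genes, Mylk fell among 18 smooth muscle genes. Among 12 enteric neuron and glia genes edgeR called 0. These lists, like those of macrophages and mast cells, did not pass camera.

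Of 108 small nucleolar RNAs 58 rose and Snora62, Snord22 and Snord89 fell on the supplemented diet (median 0.90; 65 higher and 7 lower adjusted over the list alone), with Snord87 at 2.39 ± 0.31 and Snord1b at 1.68 ± 0.21. The small nucleolar RNA list had an adjusted p = 0.139 with an estimated correlation. Of 13 mitochondrial messenger RNAs 11 rose (median 1.08; 13 adjusted over the list alone), with mt-Nd6 at 1.48 ± 0.16 and mt-Nd3 at 1.43 ± 0.19. The mitochondrial list had an adjusted p = 0.0935 with an estimated correlation. Of 9 listed small nuclear RNAs Rnu73b (1.47 ± 0.19), Rnu1b6 (2.13 ± 0.28) and Rnu12 rose (median 0.66; 4 adjusted over the list alone). Of 52 histone genes Hist2h2ac (1.39 ± 0.20), Hist1h2ad and Hist1h4d rose, without the list passing. Of 16 lists past camera, those of antimicrobial genes (0.00932), goblet cells (0.0161), small nuclear RNAs (0.0378) and Paneth cells (0.0491) also passed with an estimated correlation.

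Limma voom called 2629 genes higher and 2628 lower on the supplemented diet, an adjusted p under 0.01 left 577 and 465, and 1053 and 874 were called without the 3 libraries under 4 M counts. Counts of higher and lower genes were 805 and 753 without unirradiated replicate 1, 830 and 755 without unirradiated replicate 4, 807 and 627 without irradiated replicate 2, 846 and 689 without irradiated replicate 3, and 1821 and 1806 without irradiated replicate 4. The regenerating list did not pass without unirradiated replicate 4 (0.41) nor the p53 list without unirradiated replicate 2 (0.09), and the p53 median was 0.07 without unirradiated replicate 1, 0.26 without unirradiated replicate 3 and 0.07 without irradiated replicate 4. Calls of genes ended without unirradiated replicates 1 or 4 or irradiated replicates 1, 2 or 3 for Slc2a5, whose value was -3.23 without irradiated replicate 4, and without irradiated replicates 2 or 3 for Cyp4f14, whose value was -2.27 without irradiated replicate 4. They also ended without unirradiated replicates 1, 3 or 4 or irradiated replicates 1, 2 or 3 for Cbs (1.66 to 2.51 over the alternatives), and without unirradiated replicates 2 or 3 or irradiated replicates 2, 3 or 4 for Pou2af1 (-1.30 to -0.91).

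The responses to irradiation on the diets were compared directly, without a library in common. The called genes had 722 higher on both diets, where 94.7 would be shared by independent lists, and 612 lower on both, where 78.6 would be. Across the 16558 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.69, a Spearman rho of 0.695 and a covariance of 0.326. Of the genes called on the adequate diet, 98.5% had the same sign on the supplemented diet, and 97.1% the other way round. Cela2a, a pancreatic elastase, was called in opposite directions, at -1.71 ± 0.55 on the adequate (adjusted p = 0.0467) and 1.85 ± 0.56 on the supplemented diet (0.0353). This pair of calls held in DESeq2 (0.043 and 0.0337) but not without the 3 libraries under 4 M counts (0.108 and 0.0571), and it held in only 4 of the 16 fits that each left out 1 library. The call on the adequate diet ended without its unirradiated replicates 1 (adjusted p = 0.0766), 3 (0.2) or 4 (0.0645) or its irradiated replicates 1 (0.135), 2 (0.077) or 4 (0.119). The call on the supplemented diet ended without its unirradiated replicates 1 (0.11), 3 (0.0797) or 4 (0.102) or its irradiated replicates 2 (0.0706), 3 (0.0918) or 4 (0.0558). The shared count was 869 without the 3 libraries under 4 M counts, 856 without irradiated replicate 1 of the adequate diet and 869 without irradiated replicate 2 of the supplemented diet.

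**Figure D3:**
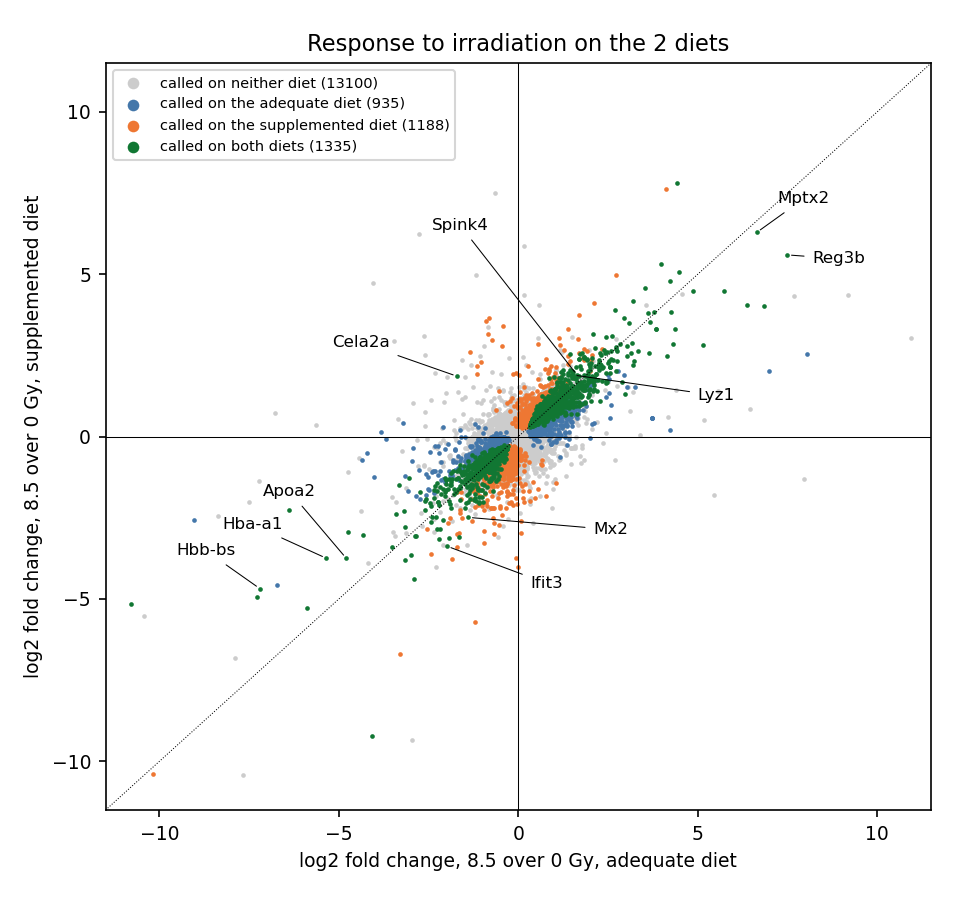
Log2 fold change of each of 16558 genes, 8.5 over 0 Gy, on the adequate diet (x axis) against the supplemented diet (y axis), with colours for the diets on which a gene was called and a dotted line of equal change. Antimicrobial and Paneth cell genes such as Reg3b (7.49 and 5.59) lie far to the upper right and globins such as Hba-a1 (-5.35 and -3.75) to the lower left.

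The interaction asks whether the response to irradiation differed between the diets. No gene was called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (0 higher and 0 lower, smallest adjusted p 0.596), 738 genes had an unadjusted p under 0.05 (4.46% of those tested), DESeq2 called 0 higher and 2 lower, and limma voom called 0. The number with an unadjusted p under 0.05 was 1630 by limma voom, 1168 without irradiated replicate 4 of the supplemented diet, and 624 to 1070 without any other single library. Interferon-stimulated genes had a list median of -0.84 with all 27 members negative. For list means the exact permutation p was 0.0616, assuming no diet difference at either dose. For this list camera gave an adjusted p of 2.73e-21, and it had an adjusted p = 0.211 with an estimated correlation, with 0 of 27 members called and 6 lower adjusted over the list alone. Mx1 had -1.38 ± 0.32 and Oas2 -2.31 ± 0.60 (both adjusted p = 0.712). The 13 exocrine pancreas genes had a median of 3.25 (8 higher adjusted over the list alone, Cela2a at 3.56 ± 0.79, Pnlip at 4.47 ± 1.04), with an adjusted p = 0.211 with an estimated correlation. Both named genes rest on few counts. In the unirradiated supplemented libraries Cela2a was at 0.105 to 0.617 CPM and Pnlip at 0 to 0.209 CPM, while adequate unirradiated replicate 3 had 2.68 and 2.37 CPM. The B cell (median 0.63), red blood cell (2.36, Hba-a1 at 1.61 ± 0.54) and tuft cell lists (0.31, Sh2d6 at 1.06 ± 0.52, Avil at 0.39 ± 0.30) passed camera upwards, and the ATF4 (-0.24, Atf3 at -1.66 ± 0.51) and inflammatory lists (-0.68, Il1r2 at -0.96 ± 0.50) downwards. With an estimated correlation these lists had an adjusted p of 0.861, 0.674, 0.308, 0.269 and 0.308 in that order, and 0 of the 38 lists passed. The log2 differences were -0.46 ± 0.43 for Cdkn1a, -0.37 ± 0.25 for Mdm2, -0.20 ± 0.37 for Mki67, -0.09 ± 0.34 for Lgr5, -0.05 ± 0.32 for Olfm4, 0.38 ± 0.29 for Lyz1, -0.33 ± 0.50 for Alpi, -0.28 ± 0.20 for Mat2a and 0.11 ± 0.25 for Dnmt1, with none called. Without irradiated replicate 4 of the supplemented diet 2 genes were called lower, and 4 of the 7 lists passed without unirradiated replicate 3 of the adequate diet. The red blood cell list did not pass without irradiated replicate 3 of the supplemented (0.45) or irradiated replicate 4 of the adequate diet (1.99), nor the B cell list without unirradiated replicate 4 of the adequate diet (0.37), and its median was 0.95, 1.10, 1.07 and 1.09 without adequate unirradiated replicates 1 or 3, adequate irradiated replicate 3 or supplemented unirradiated replicate 2. The ATF4 list lost its call without adequate unirradiated replicate 3 (-0.19), supplemented unirradiated replicate 1 (-0.16) or supplemented irradiated replicate 4 (-0.18). The inflammatory list lost its call without adequate unirradiated replicates 2 (-0.67) or 3 (-0.44), adequate irradiated replicates 1 (-0.56) or 3 (-0.57), supplemented unirradiated replicate 3 (-0.43) or supplemented irradiated replicates 2 (-0.63) or 4 (-0.60). It was at -0.41 without adequate irradiated replicate 4. The tuft cell list lost its call without adequate unirradiated replicates 3 (0.40) or 4 (0.24), adequate irradiated replicates 1 (0.28), 2 (0.21) or 4 (0.28), supplemented unirradiated replicates 3 (0.28) or 4 (0.32) or supplemented irradiated replicates 2 (0.23) or 3 (0.29). It was at 0.50 without supplemented unirradiated replicate 2.

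Diet at 0 Gy asks what supplementation changed in unirradiated mice. Of 27 interferon-stimulated genes 3 were called higher on the supplemented diet, and the list had an adjusted p = 0.0773 with an estimated correlation. Ifit3 was at 342 ± 96.2 CPM against 87.0 ± 28.5 on the adequate diet (log2 fold change 1.97 ± 0.38, adjusted p = 0.0482, n = 4 per group), and Ifi204, a sensor of foreign DNA, at 11.3 ± 3.82 against 2.62 ± 0.701 CPM (2.06 ± 0.29, adjusted p = 0.0147). All 27 genes of the list had positive fold changes with a median of 0.99, and 25 were called adjusted over the list alone. The list passed camera with its preset correlation at an adjusted p of 2.88e-29. The mean of the list per library was 5.59 ± 0.169 log2 CPM on the adequate and 6.71 ± 0.214 on the supplemented diet, a difference of 1.12 (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allow).

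**Figure D4:**
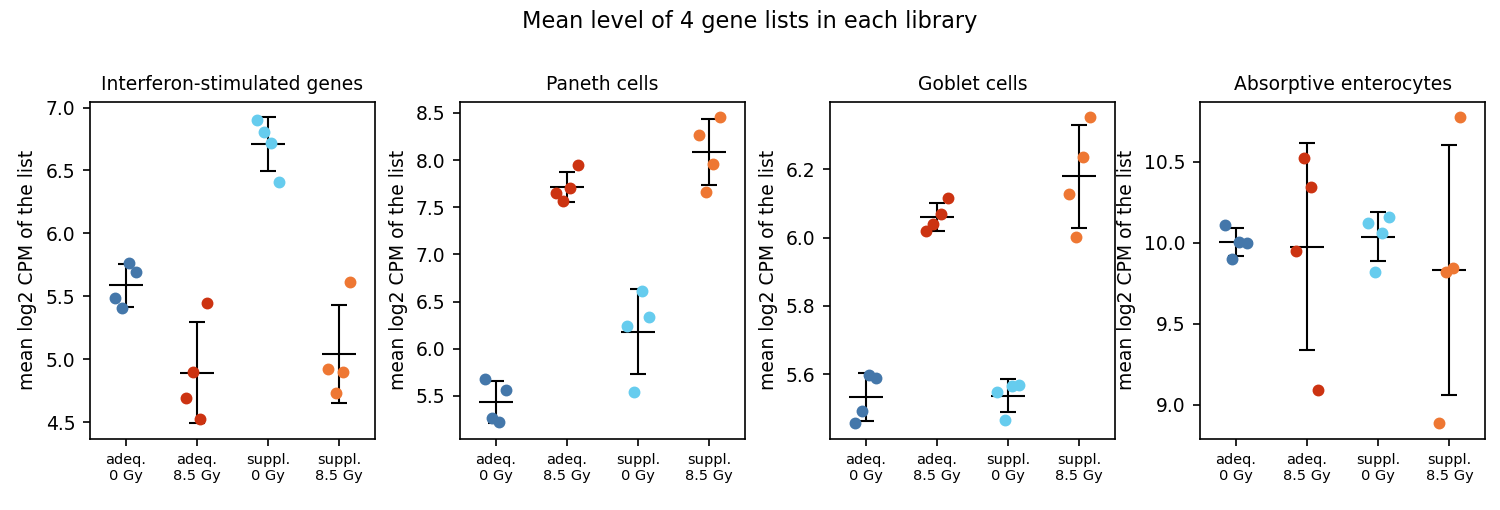
Mean log2 CPM of 4 gene lists in each library of the 4 groups. Points are libraries and bars show mean ± SD (n = 4). Interferon-stimulated genes averaged 6.71 in the unirradiated supplemented group against 5.59, 4.89 and 5.04 in the unirradiated adequate, irradiated adequate and irradiated supplemented groups.

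EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 28 genes higher and 5 lower between the diets at 0 Gy, and 1977 had an unadjusted p under 0.05. The 8 named higher genes were Ifi202b (2.11 ± 0.36), Ifi204, Ifit3, Ifit3b (1.96 ± 0.27), the virus entry inhibitor Ifitm3 (1.84 ± 0.28), Slfn5 (1.82 ± 0.31), Phf11d (1.78 ± 0.33) and AW011738 (1.57 ± 0.28), and Mx2 (1.15 ± 0.21) and Mx1 (1.15 ± 0.21) were called as list members. The lower genes were Rbm12b1 (-1.26 ± 0.24), the nuclear scaffold protein Safb (-0.54 ± 0.10) and the kinase Taok2 (-0.52 ± 0.09), and the genes ENSMUSG00000079255 and ENSMUSG00000082697, which have no symbol. Of the lists with 0 called members, those of fibroblasts (median 0.40), macrophages (0.29), Paneth cells (0.51), endothelium (0.27), inflammatory genes (0.77) and antimicrobial genes (0.36) were higher by camera and kept that call in each alternative but 1. With an estimated correlation they had an adjusted p of 0.491, 0.56, 0.491, 0.491, 0.282 and 0.0773. Members with the smallest p were Col6a1 (0.54 ± 0.18) and Bgn (0.58 ± 0.21), Ms4a7 (1.03 ± 0.32) and C1qc (0.39 ± 0.13), Mmp7 (0.63 ± 0.19), Eng (0.51 ± 0.16) and Flt4 (0.45 ± 0.17), Ccl2 (2.16 ± 0.67) and Icam1 (0.63 ± 0.22), and Reg3g (1.33 ± 0.30) and Reg3b (1.75 ± 0.40, adjusted p = 0.0863), none of them called. Without supplemented replicate 3 the macrophage median was 0.18 and the Paneth median 0.31. The lists of ATF4 (0.16, Atf3 at 1.45 ± 0.36, Slc7a5 at 0.90 ± 0.27), regenerating epithelium (0.32, Ly6a at 2.07 ± 0.42, Areg at 1.51 ± 0.35), T cells (0.22, Xcl1 at 1.72 ± 0.54, Gzmb at 0.61 ± 0.23) and S phase (0.16, Ccne2 at -0.71 ± 0.29, Cdc6 at 0.63 ± 0.26) were higher and those of exocrine pancreas (-2.03, Cela2a at -2.37 ± 0.56, Pnlip at -3.35 ± 0.82) and red blood cells (-0.65, Hba-a1 at -0.65 ± 0.29, Hbb-bs at -0.90 ± 0.57) lower by camera, with no member called. Their adjusted p with an estimated correlation was 0.301, 0.372, 0.491, 0.943, 0.491 and 0.499. The pancreas median was -0.87 without adequate replicate 3, and the list did not pass with a filter of 1 CPM in 8 libraries (-0.09). Pnlip was at only 0 to 0.209 CPM in the supplemented libraries. Calls ended without adequate replicate 3 (0.12) or supplemented replicate 1 (0.10) for ATF4, without supplemented replicates 1 (-0.51) or 4 (-0.44) for red blood cells, and without adequate replicate 3 (0.20) for regenerating epithelium, which was at 0.20 without adequate replicate 1 and 0.60 without adequate replicate 4. They ended without adequate replicate 3 (0.23) or supplemented replicates 2 (0.19) or 3 (0.20) for T cells, which were at 0.13 without adequate replicate 1, and without adequate replicates 3 (0.09) or 4 (0.13) or supplemented replicates 1 (0.15) or 2 (0.14) for the S phase, which was at 0.27 without adequate replicate 2.

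The methionine cycle list had 0 of 25 called members between the diets at 0 Gy and a median of 0.02, with Mat2a at 0.36 ± 0.14 (adjusted p = 0.318). The DNA methylation list had 0 of 18 and a median of 0.04, with Dnmt1 at 0.10 ± 0.18 (0.872), and the folate list 0 of 19 and 0.13. Cdkn1a had -0.13 ± 0.31, Mdm2 0.23 ± 0.18, Mki67 0.34 ± 0.26, Lgr5 0.08 ± 0.24, Olfm4 0.34 ± 0.23, Lyz1 0.11 ± 0.21 and Alpi -0.17 ± 0.36, with none called. All calls at 0 Gy ended without adequate replicate 1, without adequate replicate 2, without supplemented replicate 1 and without the 3 libraries under 4 M counts, where edgeR called 0 genes with 1514, 1512, 1792 and 1687 at an unadjusted p under 0.05. The totals were 15 and 12 without adequate replicates 3 and 4, 4, 8 and 49 without supplemented replicates 2, 3 and 4, 226 by DESeq2 and 195 by limma voom.

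Diet at 8.5 Gy asks what supplementation changed in irradiated mice. No gene was called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (0 higher and 0 lower, smallest adjusted p 0.486), 871 genes (5.26%) had an unadjusted p under 0.05, DESeq2 called 5 higher and 6 lower, and limma voom called 4 higher and 10 lower. The number with an unadjusted p under 0.05 was 3089 by limma voom, 2068 without adequate replicate 4 (where 1 gene was called higher), 1633 without supplemented replicate 4, and 568 (without adequate replicate 3) to 817 without any other single library. Fibroblast and matrix genes had a median of 0.38 with all 20 positive, among them Dcn (0.66 ± 0.20, adjusted p = 0.861) and Postn (0.70 ± 0.25), and Paneth cell genes one of 0.46 with all 14 positive, among them Pla2g2a (0.58 ± 0.20), Habp2 (0.46 ± 0.18) and Lyz1 (0.49 ± 0.21). Camera gave these lists an adjusted p of 3.69e-14 and 5.06e-08, and each had an adjusted p = 0.36 with an estimated correlation. Macrophage genes (median 0.26, Fcgr1 at 0.68 ± 0.26, Cd163 at 0.61 ± 0.26) and exocrine pancreas genes (1.11, Pnliprp1 at 0.68 ± 0.30, Cela2a at 1.19 ± 0.55) passed upwards too, with an adjusted p of 0.588 and 0.36 with an estimated correlation. Interferon-stimulated genes had a median of 0.16 (adjusted p = 0.103) and a difference in list means of 0.15 (exact two-sided permutation p = 0.514). The fibroblast median was 0.66 and the macrophage median 0.45 without adequate replicate 4, the macrophage median was 0.17 without adequate replicate 3, and the pancreas median 0.61 without supplemented replicate 3.

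Further lists past camera at 8.5 Gy depended on single libraries. These were cholesterol synthesis (0.18, Fdps at 0.37 ± 0.16, Fdft1 at 0.40 ± 0.18; lost without adequate replicate 1, at 0.12, or supplemented replicate 4, at 0.15), endothelium (0.15, Lyve1 at 0.60 ± 0.21, Vwf at 0.31 ± 0.15; lost without adequate replicate 3, at 0.11, and at 0.28 and 0.24 without adequate replicate 4 and supplemented replicate 1) and antimicrobial genes (0.18, Duoxa2 at 0.98 ± 0.39, Duox2 at 0.63 ± 0.28; lost without adequate replicates 3 or 4, at 0.09 and 0.34, or supplemented replicate 4, at 0.13). Goblet cell genes (0.08, Spink4 at 0.43 ± 0.14, Klk1 at 0.31 ± 0.13) were lost without adequate replicates 1, 2 or 4 (0.09, 0.11 and 0.11) or supplemented replicates 3 or 4 (0.06 and 0.02), and were at 0.14 and 0.18 without supplemented replicates 1 and 2. Mitochondrial messenger RNAs (-0.18, mt-Nd4l at -0.49 ± 0.14, mt-Nd2 at -0.34 ± 0.20) were lost without adequate replicates 1 or 4 (-0.14 each) or supplemented replicates 1 or 4 (-0.13 and -0.10), and were at -0.27 and -0.28 without adequate replicate 3 and supplemented replicate 2. Absorptive enterocyte genes had -0.10 (Slc6a19 at -0.66 ± 0.47), not called without adequate replicates 2 or 3 or supplemented replicate 1, at 0.09, 0.02 and 0.12, and at -0.28, -0.05, -0.04 and -0.49 without adequate replicate 4 and supplemented replicates 2, 3 and 4. With an estimated correlation the adjusted p of these lists was 0.588, 0.588, 0.36, 0.588, 0.702 and 0.853. Cdkn1a had -0.59 ± 0.31, Mdm2 -0.14 ± 0.18, Mki67 0.13 ± 0.26, Lgr5 -0.02 ± 0.23, Olfm4 0.29 ± 0.23, Alpi -0.50 ± 0.36, Mat2a 0.07 ± 0.14 and Dnmt1 0.21 ± 0.18. None of these was called, and the methionine cycle list had 0 of 25 called members and a median of 0.07.

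Other groupings of the libraries matched the numbers of lists past camera with its preset correlation in all 5 comparisons. Some keep part of the real contrast, so they give no rate of chance calls. Calls of lists rest on the members' own tests and the tests with an estimated correlation. Median, mean and test had the same sign for every list that passed camera. Without the 3 libraries under 4 M counts edgeR called 0 genes between the diets at 8.5 Gy and 0 for the interaction, with 842 and 695 genes at an unadjusted p under 0.05.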

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

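The tests of a larger share of immune cells, of a handling or batch difference and of other groupings for the interaction, given for the interferon-stimulated genes below, were chosen only after the result was seen.

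A library is listed here when the gap between it and the nearest other library of its group passed the 95% limit of Dixon's test for 4 libraries. Chance gives about 1 in 20 groups such a gap. The gap occurred in 2 of 20 groups of totals and RNA shares, in 3 of 152 groups of list means and in 44 of 580 groups of named genes. Totals were 2.57 M counts in unirradiated replicate 1 and 2.85 M counts in irradiated replicate 2 of the adequate diet, each far below the rest of its group. The list means that stood apart were lipid oxidation at 6.17 log2 CPM in irradiated replicate 4 of the adequate diet, histones at 3.78 in unirradiated replicate 1 of the adequate diet, and xenobiotic metabolism at 7.13 in unirradiated replicate 4 of the supplemented diet.

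Single genes stood apart in these libraries, with values in log2 CPM, on which -2.23 means 0 counts. Among unirradiated libraries of the adequate diet these were Defa3 (3.99), Hist2h2ac (3.64), Mcpt1 (1.53) and Ugt1a1 (7.99) in replicate 1, Ccl2 (-2.23) in replicate 2, Mdm2 (5.59) in replicate 3 and Dcn (6.15) in replicate 4. Among irradiated libraries of the adequate diet they were Cyp4f14 (8.46) in replicate 1, Jchain (6.08), Tph1 (4.36), AW011738 (-0.67) and Mx1 (3.16) in replicate 2, mt-Nd6 (7.87) and Duox2 (3.74) in replicate 3, and Apoa2 (0.70), Fbp1 (6.99), Slfn5 (5.36), Phf11d (3.66), Ms4a7 (3.45), Lyve1 (3.11) and Il1r2 (0.37) in replicate 4. Among unirradiated libraries of the supplemented diet they were Defa3 (-2.23), Timp1 (-0.46) and Pnliprp1 (1.77) in replicate 2, Ugt1a1 (7.46) in replicate 3, and Brip1 (4.20) and Slfn5 (6.03) in replicate 4. Among irradiated libraries of the supplemented diet they were Defa37 (6.63), Timp1 (0.13), Mmp7 (7.45), Alpi (8.33), Ly6a (4.25) and Pnliprp1 (0.75) in replicate 1, Mptx1 (5.35) in replicate 2, Hbb-bt (0.90) in replicate 3, and Tkfc (10.09), Fbp1 (8.47), Aldh18a1 (8.08), Zbtb33 (3.94), Rnu73b (6.72), Snord87 (10.19), Retnlb (7.26) and Dhcr7 (5.03) in replicate 4. No explanation was tested for these single values.

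The response of 7 lists to irradiation differed between the diets by camera with its preset correlation, with median log2 differences of -0.24 for ATF4, 0.63 for B cells, 3.25 for exocrine pancreas, -0.68 for inflammatory genes, -0.84 for interferon-stimulated genes, 2.36 for red blood cells and 0.31 for tuft cells. With an estimated correlation 0 lists passed. Of 100 drawn groupings of the libraries, 89 gave at least 7 lists, with up to 18 in the others, so chance cannot be excluded for this number. Nor can it for the interferon median of -0.84, whose size 11 of the 100 groupings reached, the real one included, with up to 1.55 in the others.

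The median of 0.99 of the interferon-stimulated genes on the supplemented diet at 0 Gy was weighed further. It was matched by no other of the 35 splits, whose highest was 0.76 (1 of 35, the real one). That share is the smallest these splits allow and was not adjusted for the number of patterns tested. It makes chance unlikely without excluding it. Among 3 immune cell lists the highest upper quartile of log2 change was 0.404, below 0.807, the interferon list's lower quartile. This argues against immune cells as sole cause. A part stays open, as macrophage genes rose by camera. A handling or batch difference shared by all libraries of the diet cannot be told apart from the diet, and shares of counts also moved with the diet at 0 Gy, at 2.17 against 4.68% for mitochondrial ribosomal RNA and 0.446 against 2.0% for Lars2 (exact permutation p 0.0286 each, 0.0801 adjusted), the former at 8.5 Gy as well (2.19 against 5.46%). The difference in interferon list means was 1.12 at 0 Gy and 0.15 at 8.5 Gy. The exact permutation p of 0.0616 over 4900 regroupings within dose assumes no diet difference at either dose. It decides nothing, so effects of diet and of handling both stay open.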

How the results depend on the processing

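The alternative without the 3 libraries under 4 M counts was chosen only after the data were seen, and the others before.

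Among named genes, 57 of 67 calls on the adequate diet, 59 of 69 on the supplemented diet and 0 of 13 between the diets at 0 Gy were kept under each alternative run. Among lists, not counting the estimated correlation, 16 of 18, 14 of 16, 7 of 13 (diet at 0 Gy), 4 of 10 (diet at 8.5 Gy) and 2 of 7 calls (interaction) were kept. No gene call reversed.

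For radiation on the adequate diet, an adjusted p under 0.01 called 485 genes higher and 386 lower, fewer by its construction, limma voom 1813 and 1770, and leaving out the 3 shallow libraries 624 lower. Leaving out 1 library gave 690 to 1273 higher and 541 to 1205 lower. On the supplemented diet these were 577 and 465 for the stricter threshold, 2629 and 2628 for limma voom, and 805 to 1821 higher and 627 to 1806 lower without 1 library. The genes shared between the diets numbered 496 with the stricter threshold, 869 without the 3 libraries and 856 to 1824 without 1 library.

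For diet at 0 Gy, 0 genes were higher and 0 lower by edgeR with an adjusted p under 0.01, where 1977 had an unadjusted p under 0.05, and 0 and 0 without the 3 libraries, where 1687 did. DESeq2 called 165 higher and 61 lower, limma voom 144 and 51, and a fit of the compared groups alone 111 and 28. No filter beyond 1 count gave 3 lower and a filter of 1 CPM in 8 libraries 8 lower. Without 1 library there were 0 to 45 higher and 0 to 4 lower. For diet at 8.5 Gy DESeq2 called 5 higher and 6 lower and limma voom 4 and 10, and without 1 library 0 to 1 were higher. For the interaction DESeq2 called 2 lower, and without 1 library 0 to 2 were lower. For the differences between tools and settings the cause was not tested, except that a stricter threshold lowers a count by construction. Nor was it tested why counts rose to 1821 and 1806 on the supplemented diet without irradiated replicate 4.

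With an estimated correlation 5 lists passed on the adequate diet and 4 on the supplemented diet, and 0 passed for diet at 0 Gy, diet at 8.5 Gy and the interaction. The cause of this loss was not tested. Without 1 library 4 to 10 lists passed for the interaction.

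Some list medians reversed, and the cause was not tested. Without irradiated replicate 4 of the adequate diet, G2 and M phase genes had -0.19 for radiation on that diet (-0.19 to 0.27 without 1 library) and 0.33 for the interaction (-0.17 to 0.33), and histones 0.22 for diet at 8.5 Gy (-0.20 to 0.22). Absorptive enterocyte genes for diet at 8.5 Gy had 0.12 without irradiated replicate 1 of the supplemented diet (-0.49 to 0.12) and 0.29 without the 3 libraries. Without those 3 libraries, ileal enterocyte genes had 0.40 for diet at 8.5 Gy and absorptive genes 0.17 for the interaction.

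A fit of the compared groups alone was not run for the interaction, which needs all 4 groups. No paired analysis was possible because the labels pair no libraries. The 3 shallow libraries had 2.57, 2.85 and 3.43 M counts, and counts without them are given above.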

Other observations

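The gene families here, and the tests on the other short RNAs, the hosts of small nucleolar RNAs and the nuclear respiratory chain, were chosen only after the results were seen.

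Families beside the fixed lists were screened as well, 49 in all, of which 44 had at least 5 tested members, with adjustment over those 44. Some share members with the fixed lists, such as Saa3, Ly6a, Atf3 and the small nucleolar RNAs, so they are not all separate findings. The families of this paragraph did not pass with an estimated correlation on either diet. Genes of fructose uptake and breakdown and targets of the sugar sensor ChREBP were lower, with 12 of 15 called on the adequate diet (median log2 fold change -1.42) and 7 of 15 on the supplemented diet (-1.39). The irradiated libraries of the supplemented diet spread widely (family mean 6.71 ± 0.766 log2 CPM, highest 7.84, against a lowest of 7.89 without irradiation). Irradiated replicate 4 there had Tkfc at 1088 CPM (123 to 171 in the others) and Slc2a5 at 570 CPM (50.2 to 114). Mlxipl, which encodes ChREBP, had -1.87 ± 0.23 and -1.42 ± 0.23, and Khk, the first enzyme of fructose breakdown, -1.61 ± 0.37 and -1.53 ± 0.37. Ribosomal protein genes were higher, with 33 of 79 called higher on the adequate diet, where Rps27l and Rps4l were lower, and 37 on the supplemented diet, where Rps4l was lower (medians 0.57 and 0.61). Complement and acute-phase genes were higher, with 6 and 7 of 13 called (0.88 and 1.37), among them Cfi at 2.61 ± 0.20 and 3.10 ± 0.195 and Saa3 at 4.21 ± 0.86 and 4.78 ± 0.74. With an estimated correlation the adjusted p lay at 0.249 and 0.299 for fructose genes, 0.314 and 0.372 for ribosomal proteins, and 0.249 and 0.172 for complement genes, on the adequate and supplemented diets.

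A single family passed with an estimated correlation, and in a single comparison, the Ly6 genes for diet at 0 Gy (adjusted p 0.0178). Of 6 tested genes 5 were positive, with a median of 0.91, and edgeR called Ly6c1 higher (1.11 ± 0.21, adjusted p = 0.0404), while Ly6a had 2.07 ± 0.42 (0.0609) and Ly6e 2.05 ± 0.44 (0.0744). Adjustment was over the 44 families within each comparison and not over the 5 comparisons. After irradiation on the supplemented diet 4 of the 6 were called lower (median -1.59, 0.142 with an estimated correlation), and the interaction was negative in all 6 (-1.0, 0.0606). The sign of each of these medians was kept under RLE and upper-quartile factors, and fits without single libraries were not run for families.

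Immediate early genes, which respond to stimuli within minutes, had a median of 0.67 between the diets at 0 Gy, with 0 of 19 called by edgeR (adjusted p 0.384 with an estimated correlation). After irradiation the median was 0.43 on the adequate diet, with Klf6 called higher (0.848), and -0.69 on the supplemented diet, with Nr4a1, Atf3, Egr1, Zfp36, Junb and Ier2 called lower (0.457). Their interaction median was -1.08 (adjusted p 0.411 with an estimated correlation). MHC class I genes had 10 of 19 lower and H2-M2 higher on the supplemented diet after irradiation (-0.74, 0.254 with an estimated correlation), with H2-T24 at -1.88 ± 0.26. Mitochondrial transfer RNAs were lower on the supplemented diet at 8.5 Gy in all 20 genes (-0.82, 0.207 with an estimated correlation), with 0 called. Small nucleolar RNAs of the C/D box class had 48 of 71 higher on the adequate and 47 on the supplemented diet (1.24 and 1.07), and those of the H/ACA class 12 and 11 of 37 (0.50 and 0.44), while the lower ones are those named in the report. The adjusted p with an estimated correlation was 0.249 and 0.252 for the C/D class and 0.504 and 0.457 for the H/ACA class, and the difference between the classes was not tested. Under RLE and upper-quartile factors these family medians kept their signs in the comparisons given here.

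Higher small nucleolar RNAs after irradiation were weighed against technical explanations. More short RNA of every class would raise the other RNA genes of at most 300 nt, and the higher of their medians on the diets was -0.198 over 160 genes (95% bootstrap interval -0.331 to -0.054), which argues against a rise of every class. Among them, 54 small nuclear RNA genes (-0.206 and -0.06) and 61 microRNA genes (-0.309 and -0.41) had negative medians. Mitochondrial transfer RNAs (0.75 and 0.06) and the fixed list of small nuclear RNAs (0.97 and 0.66) had positive medians, so a rise of some short classes stays open. Library scaling stays open, since RLE and upper-quartile factors moved the fold changes by a median of at most 0.013 and so could not decide (lowest list median 0.894). Higher levels of the host transcripts cannot be told apart from a change in the small nucleolar RNAs themselves, since 7 hosts had a lower median of 0.325 with an interval of -0.103 to 1.43. A change in the cells of irradiated mice stays open as a hypothesis.

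Mitochondrially encoded messenger RNAs were higher after irradiation, and nuclear genes of the respiratory chain may move the other way. Their median over 89 genes was -0.312 on the adequate and -0.315 on the supplemented diet, lower than all 10000 random lists matched for length and level. Such lists ignore correlation between genes, and with an estimated correlation the whole family of 93 genes (medians -0.312 and -0.299) had an adjusted p of 0.249 and 0.299, so this stays a hypothesis. Exceptions called higher were Cox7a2l on both diets, Atp5g2 on the adequate and Ndufs6b on the supplemented diet. More short transcripts in the libraries of irradiated mice would raise nuclear genes as short as the mitochondrial ones, and the higher of their medians was -0.032 over 4974 genes (-0.047 to -0.016), which argues against it.

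Other groupings of the same libraries were set against the real one. None matched the genes called for radiation on the adequate diet (1 of 35 splits, the real one, 2270 against at most 56) or on the supplemented diet (1 of 35, 2523 against at most 135). None matched those for diet at 0 Gy (1 of 35, 33 against at most 1) or the overlap between the diets (1 of 100, 1334 against at most 0). A share of 1 in 35 is the smallest that these splits allow. It was not adjusted for the number of patterns tested, so it makes chance unlikely without excluding it. The calls at 0 Gy also ended without adequate replicates 1 or 2 or supplemented replicate 1. For the genes of diet at 8.5 Gy (35 of 35, 0 against at most 2169) and of the interaction (100 of 100, 0 against at most 263) a real count of 0 is matched by any split, so these say nothing on chance. There edgeR called 0 genes with 871 and 738 at an unadjusted p under 0.05. Without irradiated replicate 4 of the adequate diet the 871 became 2068, and without that of the supplemented diet 1633, where the 738 became 1070 and 1168. The split of the irradiated libraries that calls 2169 genes exchanges replicate 4 of the adequate with replicate 4 of the supplemented diet, and the other splits called at most 1. An exchange of these 2 labels would thus change the count of 0 at 8.5 Gy. The split was picked from 35 for its count, however, and shows neither an effect of the diet nor an exchange. Their shares of mitochondrial ribosomal RNA (3.78% and 1.28%, others of their groups 5.49 to 6.85% and 2.0 to 2.87%) are ordered as labelled. Their small nucleolar RNA shares (10.7% and 7.73%, others 7.18 to 8.3% and 11.1 to 14.1%) are ordered the other way. An exchange thus stays open and was not tested further. Among irradiated libraries the mean of the absorptive enterocyte list was 9.95, 10.52, 10.34 and 9.09 log2 CPM in adequate replicates 1 to 4. In supplemented replicates 1 to 4 it was 8.89, 9.82, 9.84 and 10.77. The split with 2169 calls sets the higher of these means against the lower ones without overlap. Whether its calls follow this difference or the diet was not tested. For the numbers of lists the splits cannot judge chance, with 12 of 35 splits (18 against at most 24), 13 of 35 (16 against 21), 3 of 35 (13 against 14), 28 of 35 (10 against 18) and 89 of 100 (7 against 18).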
